A study of Homo sapiens with 8 samples.

How the data were processed

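Per the labels' protocols, MDA-LM2 cells with a control or a TARBP2 short hairpin RNA were lysed, the nuclear fraction was bound to a rabbit antibody against m6A on protein A beads, and bound RNA was eluted with N6-methyladenosine. Ribosomal RNA was removed before libraries were made with a directional ScriptSeq kit. Whether input RNA came from the nuclear fraction is not given in the sources used here, and the IgG control that the protocol mentions was not used here. The deposited count table held raw read counts (whole numbers, unit: count) per peak, with the same peaks counted in all 8 libraries. The submitters' processing notes name cutadapt, Bowtie2 version 2.3, edgeR and the genome build hg19; the peak caller, the counting tool, its use of strand and its treatment of reads that align to several copies of a sequence are not given in the sources used here. Counts in repeated sequence, and in pairs of peaks on opposite strands, are therefore uncertain.

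The authors' deposited peak list gave a position, a strand and a score (unit: score) per peak for the series as a whole, and the score was the same for all peaks, so it ranked nothing. Positions are in hg19, printed counting from 1. The annotation at hand was of GRCh38, and on 14 chromosomes a peak ended beyond its last gene, so no position was matched to a gene and no gene name, exon or intron is given. For the same reason the gene lists fixed before the data were examined (m6A writers, erasers and readers, RNA surveillance, small RNA pathway, splicing, interferon-stimulated genes and others), the comparison of intronic with exonic peaks, and the levels of TARBP2 and other named genes were not analysed here. The list held 11773 peaks, and 11662 peaks were counted; 114 listed peaks had no counts and 3 abundant counted peaks had no position, with a median of their mean counts of 35083. Peaks were multiples of 200 bases, and 83.8% were 200 bases long. Reads in no peak, kept as 1 line of the count table, were left out of library sizes and tests and made up 66.2% to 70.5% of a library.

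The median over peaks of the mean count per library was 12.1, and 70.3% of peaks had a mean under 20. In the shallowest library the share of counts in peaks was 29.5%, with a 95% Wilson interval of 29.5% to 29.6%; such intervals cover counting error only. Replicates were compared by a chi-square of their counts over peaks with at least 10 summed counts. Chi-square per degree of freedom was 3.62 for control input, 1.37 for control MeRIP, 1.27 for knockdown input and 2.27 for knockdown MeRIP. Each pair thus differed by more than sampling noise and was kept as 2 libraries. At peaks with summed counts of 1000 or more, the values were 78.1, 2.56, 8.32 and 28.8 in the same order. The fit shared its estimate of spread over all 4 groups, so it did not follow these differences between groups.

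Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) with 1 mean per group, all 8 libraries in the fit and TMM scaling. A filter for low counts by group (filterByExpr) left 9663 peaks, with a common dispersion of 0.0109. The contrasts were MeRIP against input in each arm, the difference between both (interaction), and knockdown against control in input and in MeRIP. P-values were adjusted by the method of Benjamini and Hochberg over the tested peaks of each contrast, with a threshold of 0.05. SE is the size of the log2 change divided by the square root of the F statistic. CPM values are TMM-scaled. For the change in enrichment, the input and control enrichment, the peaks named are among the 10 with the smallest p in each direction, a rule fixed before the data were examined, as were these tests and the first alternatives below. Fisher's test on the overlap of both arms was added afterwards.

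Kinds of peaks were set after the data had been seen, from positions and the mean over all libraries: pairs overlapping by any base on opposite strands with at least 3-fold between their means, peaks with a peak on the same strand within 10 kb, and isolated peaks above or below a mean of 100. Peaks of such pairs were put in the strand kinds even if they had neighbours. Sets were tested with camera (limma 3.58.1), at a preset correlation of 0.01 and with an estimated one, and adjusted over the kinds of peaks. Tables and intervals were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

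The fit was tested on simulated data, with counts for the 9663 tested peaks drawn from the real means and library sizes and 200 of them changed. For control enrichment 23.5% of 2-fold and 72.0% of 4-fold changes were recovered, for the interaction 3.50% and 47.0%, and for input 28.5% and 72.5%. False calls made up at most 6.00% of calls in these simulated data. In the real data more than 200 peaks were called: 2577 for control enrichment, 1542 for the interaction and 599 for input. The simulation therefore does not give the share of false calls in the real data.

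Alternatives were DESeq2 1.42.0, limma-voom, the total count in peaks in place of TMM, TMM within input and within MeRIP libraries, no filter for low counts, at least 20 counts in at least 4 libraries, the replicate number as a block, each library left out in turn, only the 4 libraries compared, and an adjusted p under 0.10. Added after the data had been seen were library totals that include the reads in no peak, leaving out peaks that overlap on opposite strands, leaving out peaks with a mean of 1000 or more, the control MeRIP libraries summed as 1, counts summed over loci of peaks no more than 10 kb apart on 1 strand, and a fit of peaks with neighbours alone. Calls of the member peaks of loci, expected overlaps within kinds of peaks, and the correlation of both strands across pairs were added then as well. Under TMM the median log2 change over all peaks lay between 0.00 and 0.02. With the total count in peaks it was 0.36 in input and 0.33 in MeRIP; with totals that include the reads in no peak it was -0.14 for control enrichment, 0.20 for the change in enrichment, 0.31 in input and 0.51 in MeRIP. Directions are relative to these shifts.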

Results

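MDA-LM2 cells, a lung-metastatic derivative of the MDA-MB-231 breast cancer line, carried a control short hairpin RNA or one against TARBP2, a double-stranded RNA-binding protein best known as a partner of Dicer. MeRIP-seq sequences RNA recovered with an antibody against N6-methyladenosine (m6A), the most common internal base modification of mRNA, beside the input RNA. The series held 8 libraries in 4 groups of 2: control input, control MeRIP, knockdown input and knockdown MeRIP. Library totals ranged from 3928122 to 7031779 counts, and 1160553 to 2246442 of a library's counts lay in 11662 peaks. The submitters' list names these m6A peaks, but being listed does not mean enrichment in MeRIP. Of those tested, 1124 were called higher and 1453 lower in MeRIP than in input in control cells. In knockdown cells 647 were called higher and 195 lower. The control MeRIP replicate 2 library was the shallowest. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Peaks are named by their hg19 position and strand; genes, exons and introns under them were not analysed here, and neither was the level of TARBP2 itself, so the knockdown was not checked.

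The comparison of immunoprecipitated with input RNA asked which peaks the antibody recovered, and whether this differed on knockdown. Peaks fell into kinds by position and mean count. Of the 9663 peaks tested, 6283 outside the strand pairs given next had another peak on the same strand within 10 kb (peaks with neighbours). In places where peaks overlapped on opposite strands and differed at least 3-fold in mean count, 276 were the weaker strand and 286 the stronger strand of such a pair. The remaining peaks had none on the same strand within 10 kb, 187 with a mean of 100 counts or more (isolated abundant peaks) and 2628 below that. Overlaps on opposite strands with less than 3-fold were not counted as pairs, so peaks of the other kinds can have such an overlap. The 3 abundant peaks without a listed position entered no kind. These kinds were set after the data had been seen, without use of the groups. Counts were concentrated in few peaks: the 100 most abundant held 69.1% to 79.7% of the peak counts of a library.

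In control cells the weaker strand of opposite-strand pairs and isolated abundant peaks were mostly lower in MeRIP than in input under each scaling tried. Whether more peaks with neighbours were higher or lower turned with the scaling. The peak at chr11:108143201-108143400 (plus strand) rose from 552 ± 9.24 CPM in input to 4446 ± 65.0 CPM in MeRIP (SD, n = 2), a log2 enrichment of 3.01 ± 0.12 (SE). A second peak of the same region, chr11:108139201-108139400 (plus strand), was enriched by 1.91 ± 0.15, and chr5:131926601-131927000 (plus strand) by 2.64 ± 0.20. The stronger-strand peak at chr19:24183601-24183800 (minus strand) rose from 7569.7 ± 2023 to 34208 ± 147 CPM, and that at chr5:71146601-71147000 (plus strand) had a log2 enrichment of 1.23 ± 0.08. At the weaker-strand peak chr1:91852601-91853200 (plus strand), by contrast, MeRIP held 282 ± 9.82 CPM against 3339 ± 29 CPM in input, a log2 value of -3.56 ± 0.11.

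Across all tested peaks of control cells, edgeR's quasi-likelihood test called 1124 peaks higher and 1453 lower in MeRIP than in input at the adjusted threshold, 2577 together. DESeq2, run without the filter for low counts on 11662 peaks, called 1244, with 365 higher and 879 lower. Peaks with neighbours had 709 higher and 454 lower, while the weaker strand had 5 higher and 237 lower, with a median log2 value of -3.10. Isolated abundant peaks had 14 higher and 152 lower. The 10 enriched peaks with the smallest p spanned log2 values of 1.03 to 3.01, and the 10 depleted ones -4.19 to -2.75. With library totals that include the reads in no peak, the split was 848 peaks higher and 1705 lower, and peaks with neighbours turned to 510 higher and 622 lower. DESeq2 called 195 higher and 153 lower among peaks with neighbours. In a fit of peaks with neighbours alone there were 560 higher and 554 lower. Leaving out 1 library moved all calls to 641 higher and 1359 lower without control input replicate 1, 727 and 1316 without control input replicate 2 and 618 and 956 without control MeRIP replicate 1. Peaks with neighbours then had 389 higher and 367 lower without control input replicate 1, 427 and 427 without control input replicate 2 and 348 and 215 without control MeRIP replicate 1.

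In knockdown cells the weaker strand and isolated abundant peaks were mostly higher in MeRIP than in input under each scaling tried. The peak at chr11:108143201-108143400 (plus strand) was still higher in MeRIP, 2773 ± 290.4 against 1033 ± 36.3 CPM (SD, n = 2), with a log2 enrichment of 1.42 ± 0.11 (SE). Its neighbour chr11:108139201-108139400 (plus strand) had 1.67 ± 0.14, and chr5:131926601-131927000 (plus strand) had 1.59 ± 0.18. The weaker-strand peak chr1:91852601-91853200 (plus strand) rose from 2525 ± 34.8 CPM in input to 5769.6 ± 68.2 CPM in MeRIP, and chr19:24183601-24183800 (minus strand) fell from 5466 ± 477 to 3316 ± 363 CPM.

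In knockdown cells the same test called 647 peaks higher and 195 lower in MeRIP than in input, 842 together, against 377 by DESeq2. The weaker strand had 156 higher and 1 lower, isolated abundant peaks 110 and 14, and peaks with neighbours 126 and 94. DESeq2 called 84 higher and 0 lower on the weaker strand and 40 and 18 among peaks with neighbours, and with at least 20 counts in 4 libraries the latter turned to 75 and 106. Of the peaks enriched in control cells, 120 were also enriched in knockdown cells, against 75.3 for independent lists (Fisher's exact test across peaks, p = 1.1e-07). Kinds of peaks differed: 68 against 14.2 peaks with neighbours and 45 against 24.9 isolated peaks of low count were shared, but fewer than for independent lists among stronger-strand peaks (3 against 13.2, exact p = 1.4e-04) and isolated abundant peaks (3 against 8.24, exact p = 0.00419). The log2 ratios of both arms had a Pearson r of -0.126 across all tested peaks and 0.154 across peaks with neighbours, and peaks are not independent replicates. In control cells lower and in knockdown cells higher were 421 peaks, against 97.3 for independent lists of all peaks and 294 for lists independent within each kind. Leaving out 1 library moved these overlaps by over 1.5 times as follows, the shared enriched peaks numbering 58 without knockdown input replicate 1, 61 without knockdown input replicate 2, 68 without knockdown MeRIP replicate 1 and 71 without knockdown MeRIP replicate 2, and the 421 peaks becoming 268 without knockdown input replicate 2 and 259 without knockdown MeRIP replicate 2. Shared peaks with neighbours came to 45 without control MeRIP replicate 2, 36 without knockdown input replicate 1, 35 without knockdown input replicate 2, 38 without knockdown MeRIP replicate 1 and 41 without knockdown MeRIP replicate 2. The calls in knockdown cells came to 401 higher and 99 lower without knockdown input replicate 1, 360 and 109 without knockdown input replicate 2, 482 and 105 without knockdown MeRIP replicate 1 and 363 and 111 without knockdown MeRIP replicate 2. Weaker-strand peaks then had 100 higher and 1 lower without knockdown input replicate 1 and 98 and 0 without knockdown input replicate 2. Isolated abundant peaks had 112 higher and 22 lower without control input replicate 1, 99 and 8 without knockdown input replicate 1 and 107 and 9 without knockdown MeRIP replicate 1. Among peaks with neighbours there were 61 higher and 34 lower without knockdown input replicate 1, 61 and 38 without knockdown input replicate 2, 74 and 40 without knockdown MeRIP replicate 1 and 68 and 38 without knockdown MeRIP replicate 2.

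**Figure D1:**
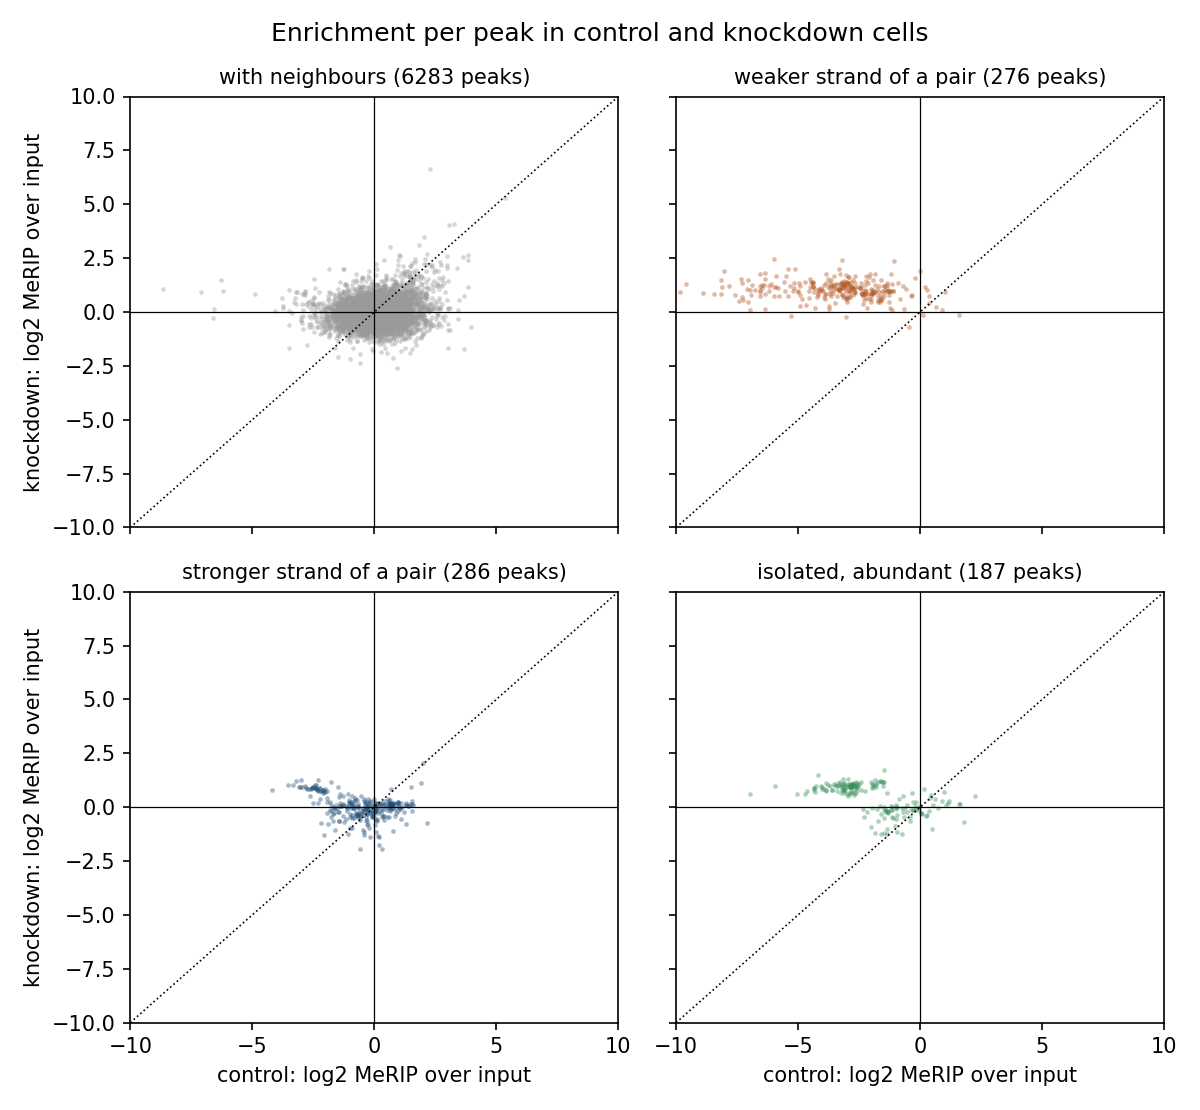
Each point is a peak, with its log2 ratio of MeRIP over input in control cells on the x axis and in knockdown cells on the y axis, in 4 kinds of peaks; the dotted line marks equal values. Most of the 276 weaker-strand peaks lie left of 0 on the x axis and above 0 on the y axis, with medians of -3.10 and 1.01, and peaks with neighbours spread wider along the x axis than along the y axis.

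The change in enrichment on knockdown is the difference between both log2 ratios. It was higher at most weaker-strand and isolated abundant peaks, under each scaling tried. At chr1:91852601-91853200 (plus strand) it was 4.75 ± 0.15 (log2, SE), at chr21:9826601-9827600 (minus strand) 4.81 ± 0.16, and at the isolated peak chr17:33478001-33478400 (plus strand) 4.98 ± 0.17. It fell at chr19:24183601-24183800 (minus strand), by 2.90 ± 0.16 on the log2 scale, and at chr5:71146601-71147000 (plus strand) by 1.46 ± 0.11. At chr11:108143201-108143400 (plus strand), a peak with neighbours enriched in both arms, it fell by 1.59 ± 0.15. The fall at the chr19 peak did not hold for its whole region: of 4 tested peaks in chr19:24183001-24186200 (minus strand), 1 was called higher and 2 lower. Among the 10 higher peaks with the smallest p, 7 were weaker-strand and 2 isolated abundant peaks, with values of 3.88 to 4.98. Among the 10 lower ones, 8 were stronger-strand peaks, with values of -2.90 to -1.08. Whether these abundant peaks lie in sequence with several copies in the genome, such as ribosomal RNA, was not analysed here, and how reads of such copies were counted is not given in the sources used here.

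**Figure D2:**
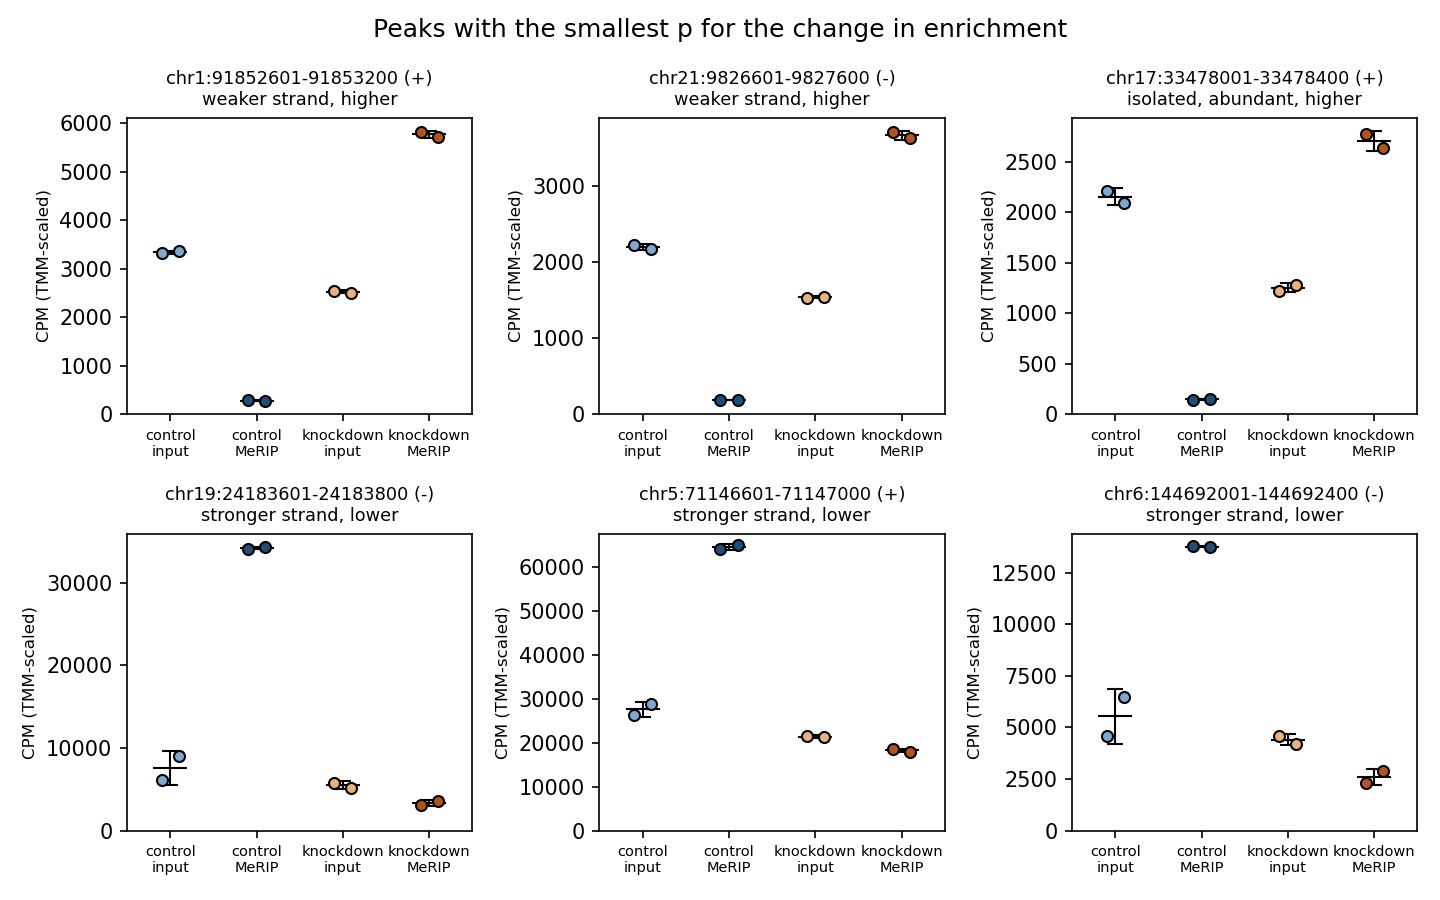
TMM-scaled CPM per library at the 3 peaks with the smallest p for a higher (upper row) and for a lower (lower row) change in enrichment; points are libraries, and bars give the mean and SD of 2 libraries. At chr1:91852601-91853200 knockdown MeRIP stood at 5769.6 ± 68.2 CPM and control MeRIP at 282 ± 9.82 CPM.

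The interaction test called 1030 peaks higher and 512 lower on knockdown among 9663 peaks (DESeq2 called 698 peaks higher and 127 lower), with 2615 at an unadjusted p under 0.05. The weaker strand had 247 higher and 2 lower, with a median of 4.29, and isolated abundant peaks 136 and 10, with a median of 2.89. Stronger-strand peaks had 108 higher and 78 lower, and isolated peaks of low count 367 and 124. DESeq2 called 95 higher and 44 lower among stronger-strand peaks, 219 and 22 among isolated peaks of low count and 43 and 52 among peaks with neighbours. Peaks with neighbours had 171 higher and 297 lower, which turned to 287 higher and 181 lower with library totals that include the reads in no peak, under which stronger-strand peaks had 124 higher and 48 lower. In a camera test against the other peaks, the weaker strand stood higher (adjusted p = 3.0e-106, and adjusted p = 0.00803 with an estimated correlation). Peaks with neighbours stood lower (adjusted p = 5.4e-09, and adjusted p = 0.00103 with an estimated correlation). Isolated abundant peaks stood higher (adjusted p = 9.4e-99, and adjusted p = 0.0327 with an estimated correlation). The call for stronger-strand peaks, adjusted p = 6.2e-07, was lost with an estimated correlation, adjusted p = 0.464. As camera compares a kind with all others, the weaker-strand and isolated abundant peaks alone can place peaks with neighbours lower. That result therefore does not show a fall at peaks with neighbours themselves. Fitted alone, which centres them, these had a median of 0.01, with 192 higher and 180 lower. With totals that include the reads in no peak, all tested peaks split into 1224 peaks higher and 325 lower, and without peaks that overlap on opposite strands into 658 peaks higher and 316 lower. The interaction calls came to 806 higher and 318 lower without control MeRIP replicate 1 and 907 and 297 without knockdown input replicate 1. Those at peaks with neighbours came to 98 higher and 167 lower without control MeRIP replicate 1, 117 and 174 without knockdown input replicate 1 and 105 and 188 without knockdown input replicate 2. Stronger-strand peaks had 96 higher and 50 lower without control MeRIP replicate 1, 97 and 48 without control MeRIP replicate 2, 100 and 46 without knockdown input replicate 1 and 105 and 50 without knockdown MeRIP replicate 1. Isolated peaks of low count had 314 higher and 68 lower without knockdown input replicate 1.

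The MeRIP libraries differed between arms in 2 shares. The first, the weaker-strand share, sums counts of the same strand pairs, so it is not separate support for the calls above. The weaker strand held 3.24% ± 0.132 of the counts of the 329 opposite-strand pairs in control input (SD, n = 2) and 3.26% ± 0.0133 in knockdown input. It held 0.589% ± 0.0161 in control MeRIP and 7.28% ± 0.219 in knockdown MeRIP. Peaks together held 32.8% ± 1.32 of a library's counts in control input, 29.5% ± 0.0578 in control MeRIP, 31.8% ± 0.242 in knockdown input and 33.4% ± 0.513 in knockdown MeRIP. For both shares, MeRIP libraries lay below both inputs of their arm in control cells and above both inputs of their arm in knockdown cells. With 2 libraries per group, no two-sided exact permutation p lies below 0.333.

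**Figure D3:**
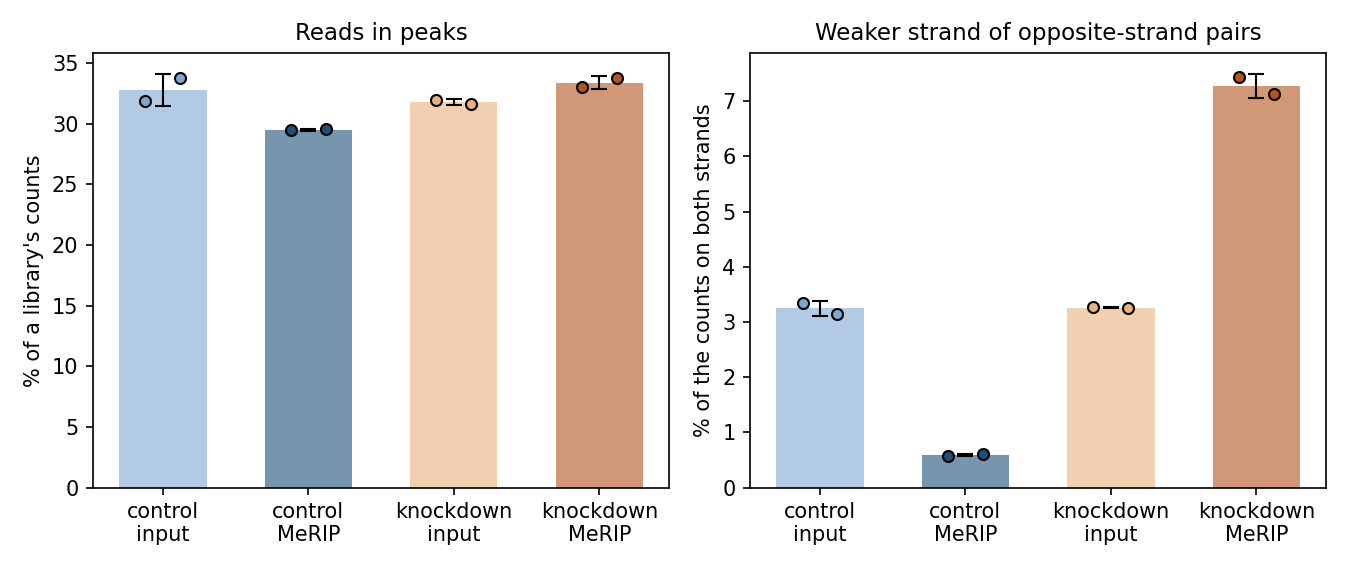
Bars give group means with the SD of 2 libraries and points give libraries, for the percent of a library's counts in peaks (left) and the percent of the counts of opposite-strand pairs on the weaker strand (right). The weaker-strand share was 0.589% in control MeRIP and 7.28% in knockdown MeRIP, with the inputs in between.

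Input RNA showed which transcribed regions changed in level on knockdown. Input fell at chr3:125058601-125058800 (minus strand), a peak with neighbours, from 244 ± 94.2 to 20 ± 2.10 CPM (SD, n = 2), a log2 change of -3.59 ± 0.22 (SE), and at the isolated peak chr3:61684801-61685000 (minus strand), with -2.44 ± 0.17. The stronger-strand peak chr15:65588401-65588600 (plus strand) fell from 988 ± 147 to 250.2 ± 0.458 CPM, and the isolated peak chr4:119200201-119200400 (plus strand), enriched in control MeRIP, fell by 1.62 ± 0.14. Input rose at chr11:108143201-108143400 (plus strand), by a log2 change of 0.90 ± 0.11, at chr3:48607001-48607400 (minus strand), by 1.69 ± 0.26 from 11.6 ± 0.375 to 37.5 ± 3.39 CPM, and at chr12:49666801-49667000 (plus strand), by 0.94 ± 0.17. The 10 higher peaks with the smallest p spanned 0.75 to 1.69, 6 of them peaks with neighbours, and the 10 lower ones -3.59 to -1.12, 6 of them on the stronger strand of a pair.

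The test of input called 154 peaks higher and 445 lower in knockdown than in control cells, and DESeq2 45 peaks higher and 278 lower. Stronger-strand peaks had 3 higher and 145 lower, with a median of -0.46; their camera test gave adjusted p = 4.1e-45, and adjusted p = 0.0612 with an estimated correlation. Weaker-strand peaks had 2 higher and 55 lower, which became 16 and 13 with the total count in peaks and 10 and 14 with totals that include the reads in no peak; stronger-strand peaks had 53 and 69 under the first and 35 and 70 under the second of these scalings. Peaks with neighbours had 91 higher and 111 lower, which turned to 563 and 39 under the first and to 398 and 41 under the second. DESeq2 called 0 higher and 33 lower on the weaker strand and 26 and 41 among peaks with neighbours. With only the 4 input libraries fitted, all peaks split into 57 and 294, stronger-strand peaks into 0 and 94, weaker-strand peaks into 1 and 35 and peaks with neighbours into 39 and 69. For all peaks the direction rested on the scaling: with the total count in peaks the split was 907 peaks higher and 205 lower, and with totals that include the reads in no peak 649 peaks higher and 209 lower. The input calls came to 97 higher and 489 lower without control input replicate 1, 31 and 251 without knockdown input replicate 1 and 50 and 205 without knockdown input replicate 2. Stronger-strand peaks then had 0 higher and 80 lower without knockdown input replicate 2. The weaker strand had 0 higher and 20 lower without knockdown input replicate 1 and 0 and 17 without knockdown input replicate 2. For peaks with neighbours these were 53 higher and 84 lower without control input replicate 2, 22 and 42 without knockdown input replicate 1 and 27 and 32 without knockdown input replicate 2.

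The level in MeRIP libraries, taken without division by input, rose on knockdown at most weaker-strand peaks under each scaling tried. The stronger-strand peak chr19:24183601-24183800 (minus strand) stood at 34208 ± 147 CPM in control MeRIP and 3316 ± 363 CPM in knockdown MeRIP, a log2 change of -3.37 ± 0.12. The isolated peak chr4:119200201-119200400 (plus strand) fell by 4.10 ± 0.16, and the weaker-strand peak chr1:91852601-91853200 (plus strand) rose by 4.35 ± 0.12. The test called 1385 peaks higher and 1361 lower, 2746 together against 1248 by DESeq2, with 264 of the 276 weaker-strand peaks higher and, among peaks with neighbours, 431 higher and 865 lower. With the total count in peaks the split was 2160 peaks higher and 756 lower, peaks with neighbours then having 972 higher and 432 lower, and with totals that include the reads in no peak it was 2765 peaks higher and 545 lower, with 1411 and 299 among peaks with neighbours. DESeq2 called 88 higher and 217 lower among peaks with neighbours. The calls in MeRIP came to 936 higher and 786 lower without control MeRIP replicate 1. Peaks with neighbours came to 177 higher and 445 lower without control MeRIP replicate 1, 270 and 557 without knockdown MeRIP replicate 1 and 327 and 570 without knockdown MeRIP replicate 2.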

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

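The library shares, the overlap of both arms and the tests of the strand pattern were chosen after the data had been seen. MeRIP and input differed in opposite directions in control and knockdown cells for 2 library shares and for some called peaks. The weaker-strand share of opposite-strand pairs, as log2 of MeRIP over input, was -2.46 in control and 1.16 in knockdown libraries, a difference of 3.62. The percent of counts in peaks, MeRIP minus input, was -3.31 in control and 1.63 in knockdown libraries, a difference of 4.94 percentage points. These 2 differences were not tested; with 2 libraries per group the MeRIP libraries of an arm lay on 1 side of both its inputs, below them in control and above them in knockdown cells. Called peaks also differed by arm: 421 were lower in control and higher in knockdown MeRIP than in input, against 97.3 for independent lists. In the reverse direction, 23 were higher in control and lower in knockdown, against 22.7. The difference between these counts was not tested. Depletion was also shared: 90 peaks were lower in both arms, against 29.3 for independent lists. Of these, 89 lay in the kinds of peaks, against 48.6 for lists independent within each kind. Peaks with more counts are more readily called in both arms, so overlaps can exceed those of independent lists for that reason. The 421 peaks by kind, observed (and expected within that kind), were 149 (134) weaker-strand, 105 (89.4) isolated abundant, 46 (24.8) stronger-strand, 109 (36.3) isolated peaks of low count and 12 (9.10) peaks with neighbours. The expected numbers within kinds sum to 294, so most of the excess over 97.3 goes with the kinds of peaks. With 1 library left out, the 421 became 268 without knockdown input replicate 2 and 259 without knockdown MeRIP replicate 2, and the 23 ranged from 13 (without knockdown input replicate 2 or control MeRIP replicate 2) to 31.

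In 94.2% of 277 tested opposite-strand pairs the weaker strand had a higher change in enrichment than its own partner, by a median log2 difference of 4.02. In input, the log2 ratio of the weaker-strand share in knockdown over control cells was 0.00712, with an SD of 0.0344 over the 4 input libraries. This argues against more opposite-strand RNA in the knockdown input. It may not cover the nuclear RNA offered to the antibody, as the fraction that input came from is not given. Reads of the partner counted on the opposite strand at a set fraction would make both strands of a pair move together, and across 91 pairs (weaker-strand mean of 50 counts or more; pairs are not independent replicates) their log2 ratios of MeRIP over input in knockdown cells had a Pearson r of -0.158 (95% interval -0.353 to 0.0494). Over the same pairs r was 0.220 (0.0146 to 0.407) for MeRIP over input in control cells and 0.387 (0.196 to 0.549) for the input change on knockdown. By rank, Spearman's rho was -0.0104 in knockdown cells, 0.378 in control cells and 0.446 for the input change. The knockdown values argue only against such reads at 1 set fraction as the whole cause. A fraction that differs between pairs need not give such a correlation and is not covered. The knockdown ratios also had a narrow range, which can keep r low. Their SD over pairs was 0.363 on the weaker and 0.436 on the stronger strand, against 1.85 and 0.943 in control cells. The control and input values go with a part of the pattern from reads of the partner, which stays open. Reads from sequence in several copies, ribosomal RNA included, and a change with TARBP2 in m6A on these RNAs also stay open and were not tested.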

How the results depend on the processing

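Settings with reads in no peak, without opposite-strand pairs, without abundant peaks or with summed control MeRIP libraries, and the counts per kind of peak, were added after the data had been seen. Of 1101 values of named peaks under alternatives, 1100 kept their direction and call and 0 changed direction; chrX:134052401-134052600 (minus strand) lost its input call with only the 4 libraries compared (log2 0.75, adjusted p = 0.0576 in edgeR). The named peaks were chosen for the smallest p in these same libraries, which favours that result, so it does not speak for other calls. Of 200 counts, 159 stayed within 1.5 times of the value reported. DESeq2 was run without the filter for low counts, on 11662 peaks against 9663 in edgeR, with its own scaling and adjusted p. It called 1244 peaks for control enrichment (2577 in edgeR), 377 for knockdown enrichment (842), 825 for the change (1542), 323 in input (599) and 1248 in MeRIP (2746). Without the filter, edgeR called 2659 for control and 864 for knockdown enrichment. In DESeq2, peaks with neighbours had 52 lower and 43 higher for the change, 195 enriched in control and 40 in knockdown. The cause was not tested. With at least 20 counts in 4 libraries, fewer peaks entered and calls came to 1618 for control enrichment and 1592 in MeRIP, 147 higher weaker-strand peaks, and 93 higher, 449 control-enriched and 75 knockdown-enriched peaks with neighbours (106 lower in knockdown MeRIP). Without opposite-strand pairs, fewer peaks again entered: 540 for knockdown enrichment, 974 for the change and 336 in input. Input calls were 1112 with the total count in peaks, where the median over peaks was 0.36, and 351 with only the 4 libraries compared; the cause of the latter was not tested. With totals that include the reads in no peak, peaks with neighbours had 181 lower and 287 higher for the change. With 1 library left out, counts ranged from 1574 to 2588 for control enrichment and 1722 to 2870 in MeRIP, both lowest without control MeRIP replicate 1. They ranged from 469 to 988 for knockdown enrichment (500 and 469 without knockdown input replicate 1 or 2, 474 without knockdown MeRIP replicate 2), 1124 to 1435 for the change (its lower calls 297 without knockdown input replicate 1 and 318 without control MeRIP replicate 1) and 255 to 586 in input (282 and 255 without knockdown input replicate 1 or 2). For peaks with neighbours they ranged from 167 to 230 lower, 98 to 179 higher, 348 to 693 control-enriched and 61 to 145 knockdown-enriched, and for higher weaker-strand peaks from 223 to 247. Lower peaks with neighbours numbered 167, 174 and 188 without control MeRIP replicate 1, knockdown input replicate 1 or knockdown input replicate 2, and higher ones 98 and 105 without the first or the last of these. Control-enriched ones numbered 389, 427 and 348 (lower 367, 427 and 215) without control input replicate 1 or 2 or control MeRIP replicate 1, and knockdown-enriched ones between 61 and 74 without any 1 of the 4 knockdown libraries. A lone library was assumed to vary like the other groups, and the filter then let 10483 to 10696 peaks in. With the replicate number as a block, calls were 2562 for control enrichment, 845 for knockdown enrichment, 1550 for the change, 624 in input and 2690 in MeRIP. Deviations of same-numbered libraries correlated between -0.104 and 0.217 across peaks over the 6 pairs of groups. These values show no strong pairing by number but cannot exclude it, as counting noise also keeps them low. The weaker-strand share was 7.28% in knockdown MeRIP when pairs had to overlap by 50%. Gene-list and intron tests, a stricter peak score and their alternatives were not run. Of the 3 contrasts simulated, depth limited the interaction most: 4-fold changes were recovered in 25.2% of peaks with a mean under 20 and in 85.7% of those with 20 to 99.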

Other observations

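The loci, their scalings, the fit of peaks with neighbours alone and the peaks chosen in 1 replicate were added after the data had been seen, and the tests of the smaller spread after the values they measure. The loci named were chosen after their values were seen. Counts were summed over loci, runs of peaks on 1 strand no more than 10 kb apart, and 989 loci of at least 3 peaks lay under no stronger locus of the opposite strand. The locus chr5:131926601-131939200 (plus strand, 3 peaks) was enriched in both arms, with a log2 value of 1.90 ± 0.15 (SE) in control and 1.49 ± 0.13 in knockdown cells; 2 of 3 tested member peaks were called higher and 1 lower in control cells, and 3 of 3 higher in knockdown cells. The longer locus chr17:48133401-48167800 (plus strand, 24 peaks) had 0.85 ± 0.11 and 0.37 ± 0.10, with 4 of 23 and 1 of 23 member peaks called higher. At chr12:123996001-123997800 (minus strand, 3 peaks) control MeRIP stood at 26.1 ± 6.40 CPM over 4.35 ± 0.507 CPM in input (SD, n = 2), while knockdown MeRIP stood at 12.8 ± 0.883 over 16.4 ± 2.08 CPM, and the change in enrichment was -2.95 ± 0.47 (1 of 3 member peaks called lower). It was 3.70 ± 0.23 at chr19:45543401-45562600 (plus strand, 4 peaks), where 1 of 3 was called higher. The locus chr6:26027401-26033600 (minus strand, 3 peaks) was enriched on knockdown, 2.02 ± 0.18 against 0.23 ± 0.20 in control cells, with a change of 1.79 ± 0.27. In knockdown cells 1 of 3 member peaks was called higher and 2 lay below 0, so the locus value rests on 1 peak. In control cells 1 member peak was called higher and 1 lower, and for the change 1 of 3 was called higher.

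Input summed over a locus rose at chr3:48605401-48614600 (minus strand, 6 peaks), from 24.6 ± 3.14 to 78.1 ± 3.97 CPM (SD, n = 2; log2 1.66 ± 0.20), and at chr21:47404201-47424800 (plus strand, 12 peaks), from 111 ± 16.4 to 213 ± 11.9 CPM (log2 0.94 ± 0.14). It fell at chr1:173833601-173837000 (minus strand, 4 peaks), from 803 ± 188 to 271 ± 9.75 CPM (log2 -1.57 ± 0.14). Of the member peaks, 4 of 6 and 5 of 12 were called higher at the first and the second of these loci, and 2 of 4 lower at the third. Over all such loci the edgeR test called 192 higher and 92 lower in control MeRIP than in input, 26 higher and 39 lower in knockdown cells, and 30 higher and 112 lower for the change. With totals that include the reads in no peak they were 107 higher and 138 lower in control cells, 43 higher and 17 lower in knockdown cells, and 65 higher and 34 lower for the change. Input had 38 higher and 62 lower with TMM and 227 higher and 16 lower with those totals.

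At peaks with neighbours more calls for the change in enrichment were lower than higher (297 lower and 171 higher), as with the total count in peaks (333 and 166), TMM within each fraction (275 and 193), and a fit without peaks of 1000 counts or more (282 and 177) or without opposite-strand pairs (215 and 178), but not with totals that include the reads in no peak (181 and 287). Those totals move the median at these peaks from -0.10 to 0.09 and that of all peaks from 0.00 to 0.20, and in a fit and TMM scaling on these peaks alone, where 48.4% of calls were lower (180 and 192), centring favours an even split. The 48.4% met the bound set for scaling by the other kinds of peaks as the source. As centring alone can give such a share, meeting the bound does not show that source. Neither result decides whether such scaling is the source, which stays open. A lower yield of the immunoprecipitation in knockdown libraries would lower nearly all enriched peaks: of 35 peaks with neighbours chosen at a log2 enrichment of at least 1 in control replicate 1 (mean of 50 counts or more), 30, or 85.7%, were lower in knockdown than in control replicate 2. That lies between the bounds set for and against it. Choosing peaks as enriched in control cells also favours a lower value in knockdown wherever the arms differ, so this share cannot test yield. Yield and a lower m6A level on knockdown cannot be told apart, as each follows the arms.

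Enrichment also spread less over peaks in knockdown cells. Over the 707 peaks with neighbours and a mean of at least 50 counts, the SD of log2 MeRIP over input was 0.73 and 0.77 in the control replicates and 0.41 and 0.43 in the knockdown replicates. Scaling moves all peaks by 1 value and so cannot change an SD over peaks. Of the peaks chosen in control replicate 1, 82.9% of the 35 enriched and 89.6% of the 48 depleted lay nearer to 0 in knockdown than in control replicate 2. Choosing peaks in control cells favours that result wherever the arms differ, with a Pearson r of 0.222 between arms and 0.854 between control replicates. It therefore does not by itself show a smaller spread. Counting noise in the control libraries would not carry over, and the chosen enriched peaks had a median log2 value of 1.14 in control replicate 2 against 0.16 in knockdown. A weaker selection by the antibody in the knockdown libraries and a change in m6A both stay open and may act together. The 11 peaks chosen as enriched in knockdown replicate 1 had medians of 1.49 in knockdown replicate 2 and 1.44 in control cells. For the 9 chosen there as depleted, the medians were -0.75 and -0.79. Of these sets, 54.5% and 33.3% lay nearer to 0 in control cells than in knockdown replicate 2.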
